A study of Homo sapiens with 6 samples.

How the data were processed

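RNA was sequenced from human ovarian carcinoma cells in 6 libraries, 3 of control cells and 3 of cells that stably express BARD1, all labelled 48 h. Per the labels' protocols, BARD1 was introduced by lentiviral transduction of OVCAR8 cells, mRNA was selected with poly(T) beads, and cDNA was primed with random hexamers. The labels' protocols name both a directional and a non-directional library, so whether counting used strand is not given in the sources used here, and reads of overlapping or antisense genes cannot be told apart. Titles and the growth protocol name the cells OVCAR8ip1, whereas the cell line tag names SKOV3ip1 and the source name and tissue tag name SKOV3ip1 tumors. Both the line and whether the material was cultured cells or tumors are therefore in conflict. The text therefore speaks of control and BARD1-expressing cells.

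The deposited table holds raw read counts per gene, whole numbers that sum to a different total in each library, for 58735 genes with their position and biotype. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with the GRCh38 (hg38) build. The notes give no role, order or options, so how reads shared between near-identical genes were counted is not given in the sources used here. Columns were assigned to libraries by the descriptions in the labels. For 27 genes the symbol in the deposited table had been turned into a date, and all 27 were named from their gene identifier. Coordinates are those of the deposited table, on GRCh38 and counted from 1.

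Total counts were 23992482, 22767552 and 21819199 in control libraries 1 to 3 and 12744310, 24349158 and 15147685 in BARD1-expressing libraries 1 to 3. A count of 0 allows up to 3 counts, which is 0.123 to 0.235 CPM (counts scaled to a library total of 1e6) across the libraries. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries within a group held identical counts, and over genes with at least 20 counts in a pair the chi-square per degree of freedom ranged from 3.41 to 8.11, above sampling noise in each of them, so all 6 libraries were kept as separate replicates. The labels call the replicates biological without saying whether they came from separate cultures or separate transductions, so p-values measure the spread between these libraries.

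Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 15400 genes, 13009 of them protein coding. Libraries were scaled by the trimmed mean of M values (TMM), and each gene was tested with the robust quasi-likelihood F test on a model of group alone, with 4 residual degrees of freedom. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene is called higher or lower at an adjusted p under 0.05. Log2 fold changes are BARD1-expressing over control, with standard errors (SE) from the same fit. Expression is given as TMM-scaled CPM, as the mean ± SD of 3 libraries per group. A fold against a group without any count is given as a lower bound, from the counts and totals pooled over the libraries of each group, with 3 counts set for the group without any. Pooling gives deeper libraries more weight, so the bound differs from a ratio to the mean CPM.

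Before the data were examined, 22 gene lists were fixed, together with the rule for the genes to be named. That rule takes BARD1, the 8 protein-coding genes with the highest and the 8 with the lowest log2 fold change among called genes with a mean of at least 5 CPM and no overlap between groups, up to 3 members of each list with the smallest p, the level of ERBB2, and the 5 genes with the smallest p. Not every gene or list it gives is described in the text. Other genes in the text were chosen after their values were seen. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, adjusted over the 22 lists. Each list test was repeated with a correlation estimated from the data and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes.

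Runs of 25 neighbouring expressed protein-coding genes (mean of at least 5 CPM) were searched for an absolute median log2 fold change of at least 0.3, after a regional pattern had been seen. Gene order was shuffled 1000 times to give chance values. The pipeline was tested on simulated counts for 15190 genes drawn from the means, dispersions and library sizes of this comparison, with 200 genes changed. It recovered 71.6% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 100% of those changed 4-fold, and 7.30% of its calls were false. The simulated genes were drawn independently and few were changed, whereas 28.96% of tested genes were called in the data. These rates therefore need not hold for the calls reported below.

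Alternatives set before the data were examined were DESeq2-style (RLE) scaling, library sizes alone, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, a replicate block, each library left out, DESeq2 1.42.0, limma-voom, protein-coding genes alone, glmTreat against a 1.5-fold change, an estimated correlation and fry. Leaving out genes of the shifted runs and thinning all libraries to an equal depth were added after the data had been seen.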

Results

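The transcriptomes of control and BARD1-expressing ovarian carcinoma cells were compared by poly(A)-selected RNA sequencing. The question was how expression of BARD1, the partner of BRCA1 in a ubiquitin ligase complex, affects pathways of tumour angiogenesis. The design cannot separate an effect of BARD1 from other differences between the control cells and the stably transduced cells. That limit holds for all genes and gene lists below. Each group had 3 libraries, with 21819199 to 23992482 counted reads per control library and 12744310 to 24349158 per BARD1-expressing library. Of 58735 annotated genes, 15400 had enough counts to be tested. Expression is given in CPM scaled by TMM as mean ± SD over 3 libraries, and log2 fold changes are BARD1-expressing over control ± SE.

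BARD1 itself (ENSG00000138376, chromosome 2, 214725646 to 214809711, GRCh38) rose from 17.9 ± 1.30 CPM in control cells to 46.3 ± 2.43 CPM in BARD1-expressing cells (SD, n = 3 each). The libraries held 414, 392 and 420 BARD1 reads in control cells and 623, 1072 and 688 in BARD1-expressing cells, and the lowest BARD1-expressing library (44.3 CPM) lay above the highest control library (19.4 CPM). The log2 fold change was 1.37 ± 0.081 (edgeR adjusted p = 4.67e-12). An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest p that 3 against 3 libraries allow. The counts do not separate the endogenous transcript from the introduced reading frame.

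In BARD1-expressing cells 14 of 22 measured inflammatory genes, 16 of 30 interferon-induced genes and 20 of 26 mitotic genes were higher than in control cells (0, 3 and 0 lower), and 13 of 22 cholesterol synthesis genes and 10 of 13 mitochondrially encoded mRNAs were lower (3 and 0 higher). These 5 lists passed camera with the preset correlation, and none of them passed (in the same order, adjusted p = 0.114, 0.172, 0.172, 0.373 and 0.313) with an estimated correlation. The chemokine CXCL8 (interleukin-8; ENSG00000169429, chromosome 4, 73740506 to 73743716) rose from 1.03 ± 0.148 to 10.7 ± 0.280 CPM (SD, n = 3 each). The matrix protein gene FN1 (fibronectin; ENSG00000115414, chromosome 2, 215360440 to 215436172) fell from 5081 ± 380 to 1075 ± 38.6 CPM (SD, n = 3 each). Most genes of chromosome 18 fell as well, by a median of 0.68 on the log2 scale, and a stretch of the long arm of chromosome 5 rose by 0.50.

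In all, 4460 genes (28.96% of those tested) differed between the groups, 2545 higher and 1915 lower in BARD1-expressing cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most differences were small, with a median absolute log2 fold change of 0.41 among the called genes, and 726 genes changed at least 2-fold, 481 of them higher and 245 lower. The groups did not overlap at 40.9% of tested genes, where chance gives 10% for 3 against 3 libraries. The 1st principal component, with 62.4% of the variance, separated the groups, and the common biological coefficient of variation within groups was 6.28%.

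The 8 protein-coding genes with the highest log2 fold change were TRO (4.28 ± 0.168), which encodes the adhesion protein trophinin, CALB1 (4.11 ± 0.153), which encodes the calcium-binding protein calbindin, ANXA8L1 (3.79 ± 0.181), KISS1 (3.55 ± 0.128), the kisspeptin gene, ZIK1 (3.51 ± 0.187), CXCL8 (3.36 ± 0.177), the scavenger receptor gene SCARA3 (3.10 ± 0.109) and RCN3 (2.83 ± 0.114). ANXA8L1 has a near-identical copy, ANXA8, so its count is uncertain. Among the 8 with the lowest were SERPINB2 (-3.25 ± 0.168), which encodes a plasminogen activator inhibitor, MARCHF9 (-2.94 ± 0.146), ZNF404 (-2.51 ± 0.163), FN1 (-2.24 ± 0.054), the formin gene FHOD3 (-2.06 ± 0.170), RBPMS (-2.01 ± 0.134) and PHF21B (-1.89 ± 0.147). By p the leading 5 were AC005244.1, FN1, RBM23 (2.45 ± 0.069), SCARA3 and KISS1. AC005244.1 (ENSG00000263648, chromosome 17, 12115547 to 12115885) is a processed pseudogene inside MAP2K4 that overlaps none of its annotated exons. It had 5762, 5756 and 5193 reads in the control libraries and 0 in each BARD1-expressing library, at least 4243-fold lower from pooled counts (2266 to 4289 with 1 library left out, edgeR adjusted p = 8.71e-24). As a pseudogene it shares sequence with its parent gene DYNLT1, so its count is uncertain.

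**Figure D1:**
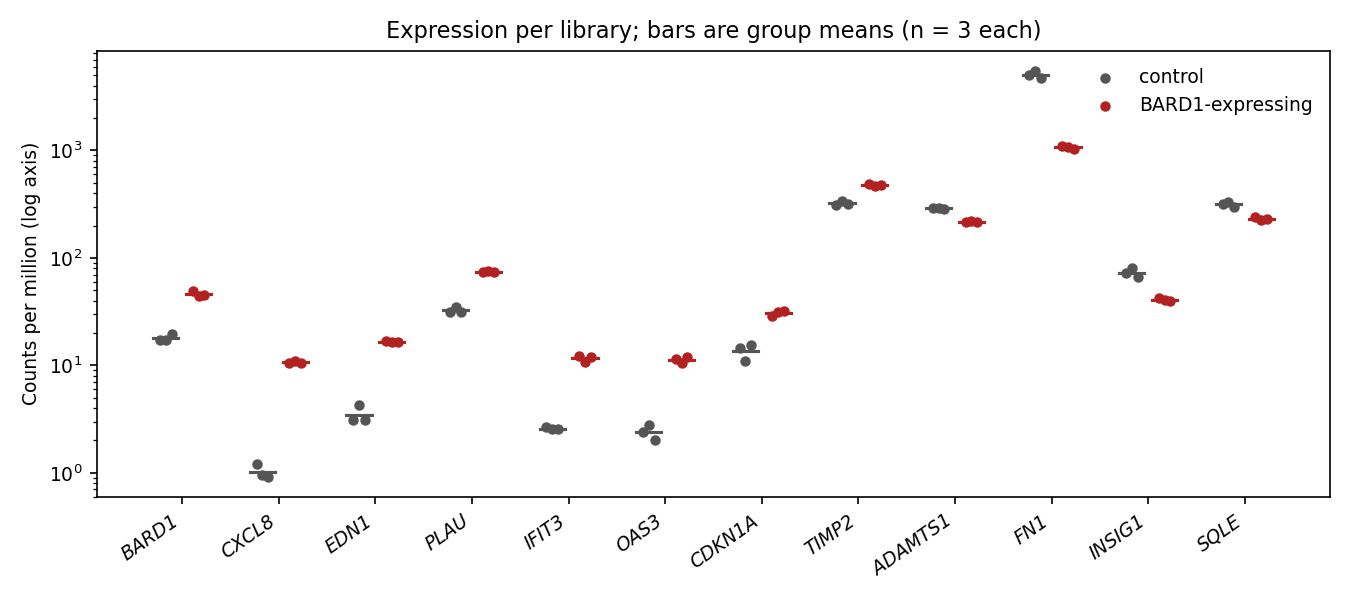
Expression of 12 genes in each library, in CPM on a log axis, with control libraries in grey and BARD1-expressing libraries in red. Points are libraries and bars are means of 3 libraries. BARD1 lies at 17.9 and 46.3 CPM, CXCL8 at 1.03 and 10.7 CPM and FN1 at 5081 and 1075 CPM in control and BARD1-expressing cells, and the groups do not overlap for any of the 12 genes.

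Changed genes were not spread evenly over the genome. On chromosome 18, 170 of 228 tested genes (74.6%) were lower in BARD1-expressing cells, against 1745 of 15172 (11.5%) on all other chromosomes (Fisher's exact test, two-sided, p = 1.05e-105, over genes, which are not independent replicates). The median log2 fold change of its 159 expressed protein-coding genes was -0.68, and it was -0.62, -0.72 and -0.67 in BARD1-expressing libraries 1 to 3, each against the mean of the controls. The best single step along the chromosome lay at 36.2 Mb, with a median of -0.47 before it and -0.98 after it, whereas the medians of the other nuclear chromosomes lay between -0.02 and 0.09. The mitochondrial genome, counted among the others above, had a median of -0.85, with 19 of 28 tested genes lower. Camera gave an adjusted p of 1.39e-37 for chromosome 18 with the preset correlation, and adjusted p = 0.127 with an estimated correlation. Runs of 25 genes shifted upwards were found on chromosome 5 (126600268 to 168472303, median 0.50), the X chromosome (153907367 to 155943769, median 0.35) and chromosome 10 (43643859 to 59247774, median 0.30). Genes within these 4 stretches are named as such in what follows. SERPINB2 and FHOD3 lie on chromosome 18 and ANXA8L1 in the chromosome 10 stretch, whose highest run (0.33) did not exceed the highest run of shuffled genes (0.34).

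**Figure D2:**
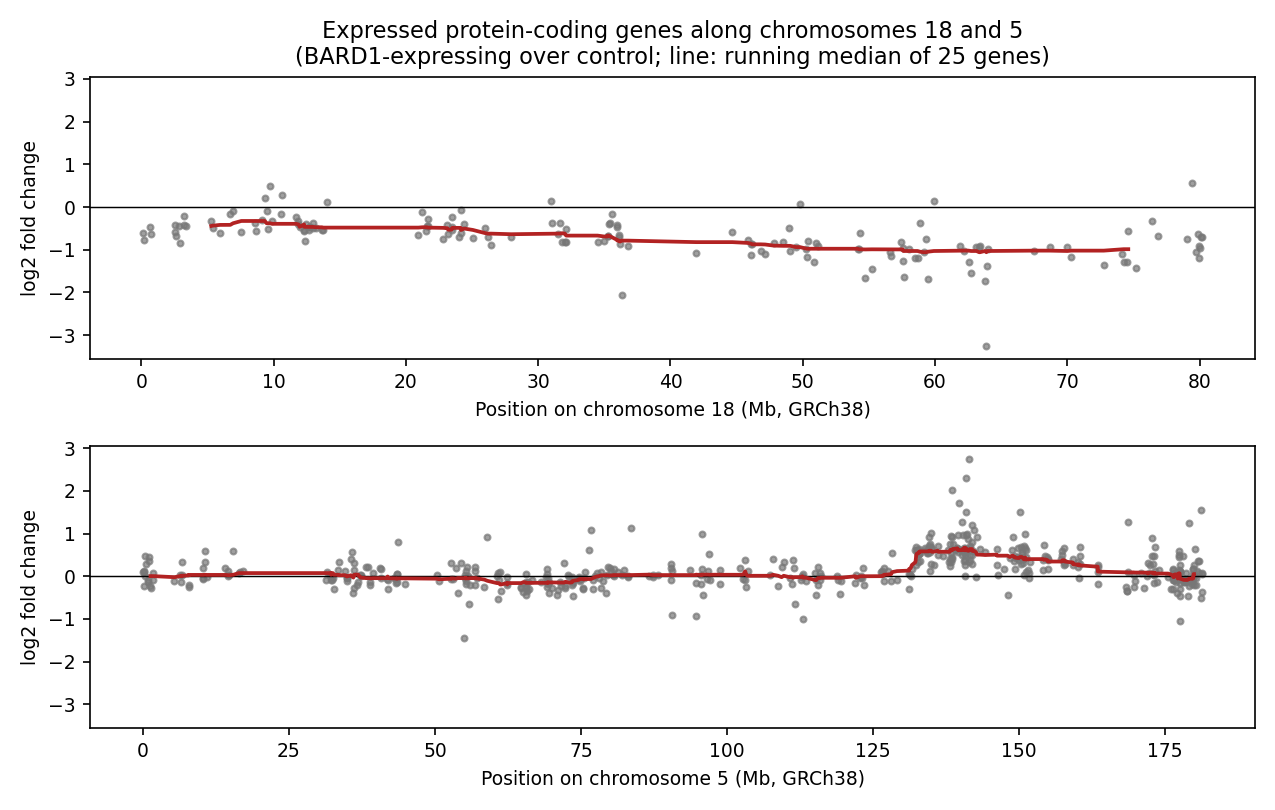
Log2 fold change (BARD1-expressing over control, vertical axis) of expressed protein-coding genes by their start on chromosomes 18 and 5 in Mb (horizontal axis, GRCh38). Points are genes and the red line is the running median of 25 genes. On chromosome 18 the line lies below 0 throughout and lower after 36.2 Mb, and on chromosome 5 it rises above 0 between 126.6 and 168.5 Mb.

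Among secreted and cell surface factors known to promote vessel growth, 16 of 34 measured genes rose and 5 fell. CXCL8 rose most clearly, PLAU, the urokinase gene, rose from 32.7 ± 2.25 to 74.1 ± 0.675 CPM, and EDN1, which encodes the vasoconstrictor endothelin, rose from 3.48 ± 0.667 to 16.7 ± 0.332 CPM (SD, n = 3 each). VEGFA rose from 9.98 ± 0.941 to 13.8 ± 1.26 CPM (log2 fold change 0.47 ± 0.114, edgeR adjusted p = 0.00258), and the related factor PGF from 0.0722 CPM, below the floor of each control library, to 0.986 CPM. The log2 fold change of PGF was 3.67 ± 0.632, and 3.15 to 5.15 with 1 library left out. The 5 members that fell were PDGFC (-0.54 ± 0.071), PDGFB (-0.91 ± 0.233), TGFB2 (-0.39 ± 0.131), FGF2 (-0.33 ± 0.061) and CCN1 (listed as CYR61, -0.14), and the calls of TGFB2 and CCN1 were lost in some alternatives. Adjusted over the list alone, 17 rose and 5 fell. The median log2 fold change of the list was 0.28, and it was above 0 in 3 of 3 BARD1-expressing libraries (camera adjusted p = 0.00823, and adjusted p = 0.172 with an estimated correlation). Of its measured members, 5 also belong to the NF-kB list and 3 to the TGF-beta list. In the same libraries 4 of 6 measured endothelial markers and 6 of 8 measured fibroblast and pericyte markers rose.

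Factors known to restrain vessel growth moved in both directions. Of 14 measured, 6 rose and 3 fell (7 and 3 adjusted over the list alone), and the list did not pass (median 0.17, camera adjusted p = 0.173, and adjusted p = 0.313 with an estimated correlation). It passed with fry (adjusted p = 0.000326) and without the filter on low counts (adjusted p = 0.0345). SEMA3F, a secreted semaphorin, rose from 4.19 ± 0.517 to 13.3 ± 1.82 CPM and the metalloproteinase inhibitor TIMP2 from 322 ± 13.5 to 477 ± 8.76 CPM, whereas the protease ADAMTS1 fell from 289 ± 2.77 to 218 ± 1.12 CPM (SD, n = 3 each). FLT1, a receptor that binds VEGFA, rose from 0.276 to 1.39 CPM. The other members that fell were TIMP1 (-0.29 ± 0.060) and COL4A3 (-1.55 ± 0.436, and -2.18 without BARD1-expressing 2).

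Most called genes of the inflammatory and interferon lists rose. Of 22 genes of the NF-kB and inflammatory list, 14 rose and none fell (15 and 1 adjusted over the list alone), with a median log2 fold change of 0.38 (camera adjusted p = 2.63e-06, and adjusted p = 0.114 with an estimated correlation). Besides CXCL8, the adhesion molecule gene ICAM1 rose from 46.5 ± 1.18 to 90.9 ± 2.64 CPM and the cytokine gene TNF from 1.16 ± 0.088 to 6.001 ± 0.705 CPM (SD, n = 3 each), and IL6 (1.40 ± 0.156) and CXCL1 (1.39 ± 0.159) rose as well. Of 30 genes of the type I interferon response, 16 rose and 3 fell (18 and 3 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 2.63e-06, and adjusted p = 0.172 with an estimated correlation). The antiviral genes DDX60, IFIT3 and OAS3 led the list, with log2 fold changes of 2.11 ± 0.126, 2.16 ± 0.145 and 2.22 ± 0.155, and IFIT3 rose from 2.57 ± 0.059 to 11.6 ± 0.843 CPM. The 3 that fell were MX2 (-0.28 ± 0.059), STAT2 (-0.33 ± 0.077), which encodes a transcription factor of the pathway, and SAMD9 (-0.27 ± 0.090), whose call was lost in some alternatives. No member of either list lay in a shifted stretch, and the medians of both lists were higher in 3 of 3 BARD1-expressing libraries.

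Mitotic genes rose while genes of DNA replication did not move as a group. In the G2 and mitosis list 20 of 26 genes rose and none fell (23 and 0 adjusted over the list alone), by a median log2 fold change of 0.21 (camera adjusted p = 1.26e-06, and adjusted p = 0.172 with an estimated correlation). The kinesin KIF20A (0.76 ± 0.052), the phosphatase CDC25C (0.93 ± 0.090) and HMMR (0.25 ± 0.061) lie in the chromosome 5 stretch, and the spindle factor TPX2 (0.42 ± 0.047) does not. In the S phase list 2 of 24 genes rose and 4 fell, with the same counts adjusted over the list alone. The thymidylate synthase gene TYMS (-0.46 ± 0.058, on chromosome 18), MCM4 (-0.29 ± 0.049), CDC6 (-0.22 ± 0.055) and MCM7 (-0.19 ± 0.048) fell, and RRM2 (0.24 ± 0.057) and MCM6 (0.23 ± 0.056) rose. The S phase list did not pass (camera adjusted p = 0.882, and adjusted p = 0.915 with an estimated correlation), and its median (0.04) was above 0 while its mean (-0.01) and its test pointed down.

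Of 28 genes of homologous recombination and the BRCA1 complexes, 2 rose and 6 fell, and the counts were the same adjusted over the list alone (median -0.11, camera adjusted p = 0.0475, and adjusted p = 0.377 with an estimated correlation). The 3 with the smallest p lie in shifted stretches, namely the end resection factor RBBP8 (-0.74 ± 0.065, chromosome 18), BRCC3 (0.36 ± 0.075, X chromosome) and RAD50 (0.57 ± 0.147, chromosome 5), and without genes of the shifted stretches the list kept its call (adjusted p = 0.0158). BRCA1 changed from 23.1 ± 1.29 to 19.4 ± 1.40 CPM (edgeR adjusted p = 0.0360), a call lost in 4 of 14 alternatives. The call of this list was lost without control 1 (adjusted p = 0.05003), control 3 (0.0929), BARD1-expressing 2 (0.147) or BARD1-expressing 3 (0.0736), and with fry (0.0810).

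Genes of the unfolded protein and integrated stress responses rose in 11 of 22 cases and none fell (12 and 1 adjusted over the list alone), with a median log2 fold change of 0.25 (camera adjusted p = 0.00388, and adjusted p = 0.172 with an estimated correlation). The cystine transporter gene SLC7A11 rose from 40.3 ± 4.39 to 102 ± 2.71 CPM, the serine synthesis gene PHGDH from 213 ± 2.51 to 337 ± 15.02 CPM and TRIB3 from 13.04 ± 1.02 to 23.1 ± 1.56 CPM (SD, n = 3 each). Cholesterol synthesis genes fell in 13 of 22 cases and rose in 3 (15 and 4 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.00784, and adjusted p = 0.373 with an estimated correlation). INSIG1, a regulator of the pathway, fell from 72.9 ± 7.05 to 40.7 ± 1.44 CPM and SQLE, which encodes squalene epoxidase, from 315 ± 19.4 to 232 ± 5.93 CPM (SD, n = 3 each). Among those that rose were SREBF2 (0.13 ± 0.049), whose call was lost in 11 of 14 alternatives, and SC5D, with no count in control libraries and at least 12.3-fold higher from pooled counts (7.97 to 12.7 with 1 library left out). The mean of this list was 0.05 from fitted values and -0.08 with SC5D at that bound, and its median was the same either way. With fry the call of the cholesterol list was lost (adjusted p = 0.0853).

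Of 29 hypoxia response genes 7 rose and 1 fell (9 and 1 adjusted over the list alone), with a median log2 fold change of 0.12 (camera adjusted p = 0.0359, and adjusted p = 0.172 with an estimated correlation). STC2, which encodes a stanniocalcin, rose from 114 ± 4.53 to 183 ± 14.9 CPM (SD, n = 3 each), and VLDLR (0.76 ± 0.131) and the collagen prolyl hydroxylase P4HA2 (0.62 ± 0.076, in the chromosome 5 stretch) rose as well. The glycolytic gene GPI (-0.21 ± 0.049) fell. The call of this list was lost without control 1 (adjusted p = 0.0598), BARD1-expressing 1 (0.0505) or BARD1-expressing 2 (0.0590), and without genes of the shifted stretches (0.0567).

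Genes of the mesenchymal and matrix list and of the epithelial list changed in both directions. In the mesenchymal and matrix list 9 of 22 rose and 4 fell (11 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.295, and adjusted p = 0.663 with an estimated correlation). FN1 had the smallest p, followed by TGFBI (0.70 ± 0.048, chromosome 5 stretch), which encodes a matrix protein, and the N-cadherin gene CDH2 (-0.70 ± 0.052, chromosome 18), and the other 2 that fell were the transcription factor genes SNAI2 (-0.61 ± 0.119) and TWIST2 (-0.55 ± 0.105). Their paralogs SNAI1 (0.60 ± 0.137) and TWIST1 (0.38 ± 0.113) rose, the call of TWIST1 being lost in 2 of 14 alternatives. In the epithelial list 8 of 16 rose and 1 fell, with the same counts adjusted over the list alone, and the list did not pass (median 0.30, camera adjusted p = 0.0526, and adjusted p = 0.208 with an estimated correlation). CLDN3, a tight junction gene, had no count in the control libraries and 1.71 ± 0.842 CPM in BARD1-expressing cells (SD, n = 3), at least 43.3-fold higher from pooled counts (27.9 to 49.9 with 1 library left out), and the protease inhibitor SPINT1 rose from 0.390 to 2.17 CPM. Of 8 markers of serous ovarian carcinoma 3 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.853, and adjusted p = 0.861 with an estimated correlation). The lineage factor PAX8 (-0.65 ± 0.061) and CRABP2 (-0.58 ± 0.122) fell, and BCAM (0.50 ± 0.071) rose, and FOLR1 (0.56 ± 0.193) and WT1 (1.43 ± 0.475) passed the test upwards, the calls of FOLR1 and WT1 being lost in some alternatives. WT1 overlapped between the groups, at 0.966 ± 0.721 CPM in BARD1-expressing cells (SD, n = 3), and its log2 fold change was 0.53 to 1.72 with 1 library left out.

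Neither TGF-beta signalling nor Notch signalling passed camera as a list, whereas both passed with fry (adjusted p = 0.0208 and 0.00216). Of 20 TGF-beta genes 7 rose and 5 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.151, and adjusted p = 0.448 with an estimated correlation). The inhibitory SMAD6 rose from 0.512 ± 0.171 to 8.61 ± 0.696 CPM and TGFB1 from 143 ± 1.67 to 202 ± 7.59 CPM, whereas the activin chain gene INHBA fell from 26.6 ± 1.795 to 13.8 ± 1.03 CPM (SD, n = 3 each). The other 4 that fell were SMAD7 (-0.48 ± 0.109, chromosome 18), LTBP2 (-0.41 ± 0.114), TGFB2 and TGFBR3 (-0.22 ± 0.078), and the calls of the last 3 were lost in some alternatives. Of 15 Notch genes 3 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.184, and adjusted p = 0.313 with an estimated correlation). HES1, a target of Notch, rose from 1.59 ± 0.397 to 8.90 ± 1.17 CPM (SD, n = 3 each), HES4 (0.47 ± 0.091) and NOTCH4 (0.82 ± 0.267) also rose, and NOTCH1 (-0.22 ± 0.066) and RBPJ (-0.18 ± 0.056) fell. The calls of NOTCH4, NOTCH1 and RBPJ were lost in some alternatives.

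Chromatin regulators and immediate early genes did not pass as lists. Of 26 chromatin and DNA methylation regulators 2 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.282, and adjusted p = 0.373 with an estimated correlation). HDAC3 (0.50 ± 0.058, chromosome 5 stretch) and the DNA methyltransferase gene DNMT3B (0.39 ± 0.101) rose, and BMI1 (-0.42 ± 0.094), DNMT1 (-0.16 ± 0.046) and KDM1A (-0.15 ± 0.049) were among those that fell, the calls of the last 2 being lost in some alternatives. Of 20 immediate early genes 5 rose and 5 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.958, and adjusted p = 0.978 with an estimated correlation), and the median (-0.04) lay below 0 while the mean (0.12) and the test pointed up. EGR1 (2.01 ± 0.145, chromosome 5 stretch), JUNB (0.66 ± 0.102), DUSP1 (0.47 ± 0.062), DUSP5 (0.42 ± 0.064) and FOSL1 (0.16 ± 0.055) rose, and IER5 (-0.32 ± 0.060), SRF (-0.27 ± 0.074), KLF2 (-0.23 ± 0.070), MYC (-0.19 ± 0.050) and JUN (-0.14 ± 0.050) fell. The calls of FOSL1, KLF2, MYC and JUN were lost in some alternatives.

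Few markers of endothelium and leukocytes were expressed enough to be measured, and those were low. The labels describe cultured cells in the growth protocol and tumors in the tissue tag, so whether other cell types were present in the material is not settled by them. Of 14 endothelial markers 6 were measured, none above a mean of 7.84 CPM, and 4 rose, with the same count adjusted over the list alone. They were ESAM (2.19 ± 0.213), TIE1 (1.89 ± 0.244), PLVAP (1.04 ± 0.161) and KDR (1.60 ± 0.483), which encodes the main VEGF receptor of endothelium and whose call was lost in 4 of 12 alternatives (list median 1.32, camera adjusted p = 0.0136, and adjusted p = 0.172 with an estimated correlation). Of 14 fibroblast and pericyte markers 8 were measured, and 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 1.14, camera adjusted p = 0.00646, and adjusted p = 0.172 with an estimated correlation). PDGFRB (1.51 ± 0.129, chromosome 5 stretch) and PDPN (1.30 ± 0.130) rose, and the collagen gene COL1A1 fell from 1054 ± 38.2 to 845 ± 24.3 CPM (SD, n = 3 each). Of 18 leukocyte markers 3 were measured, CD8A and ITGAM among them, and the list did not pass (camera adjusted p = 0.273, and adjusted p = 0.377 with an estimated correlation). CD8A fell from 1.70 ± 0.362 to 0.913 ± 0.186 CPM, a call lost in 6 of 14 alternatives, whereas ITGAM (-0.88 ± 0.425) did not pass. Adjusted over the list alone, 0 rose and 1 fell.

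The mRNAs encoded by the mitochondrial genome fell in 10 of 13 cases and none rose, with the same counts adjusted over the list alone. The respiratory chain subunit gene MT-CO2 fell from 2171 ± 262 to 983 ± 151 CPM, MT-ND5 from 1257 ± 176 to 546 ± 80.2 CPM and MT-ND6 from 352 ± 58.5 to 135 ± 20.4 CPM (SD, n = 3 each). The median log2 fold change was -0.85, lower in 3 of 3 BARD1-expressing libraries (camera adjusted p = 1.26e-06, and adjusted p = 0.313 with an estimated correlation). Mitochondrial genes held 2.05%, 1.90% and 2.40% of the counts in the control libraries and 1.16%, 1.31% and 0.965% in the BARD1-expressing libraries. The mitochondrial ribosomal RNA MT-RNR1 had 333 ± 27.0 and 344 ± 52.4 CPM in control and BARD1-expressing cells (log2 fold change 0.05 ± 0.123, edgeR adjusted p = 0.805).

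**Figure D3:**
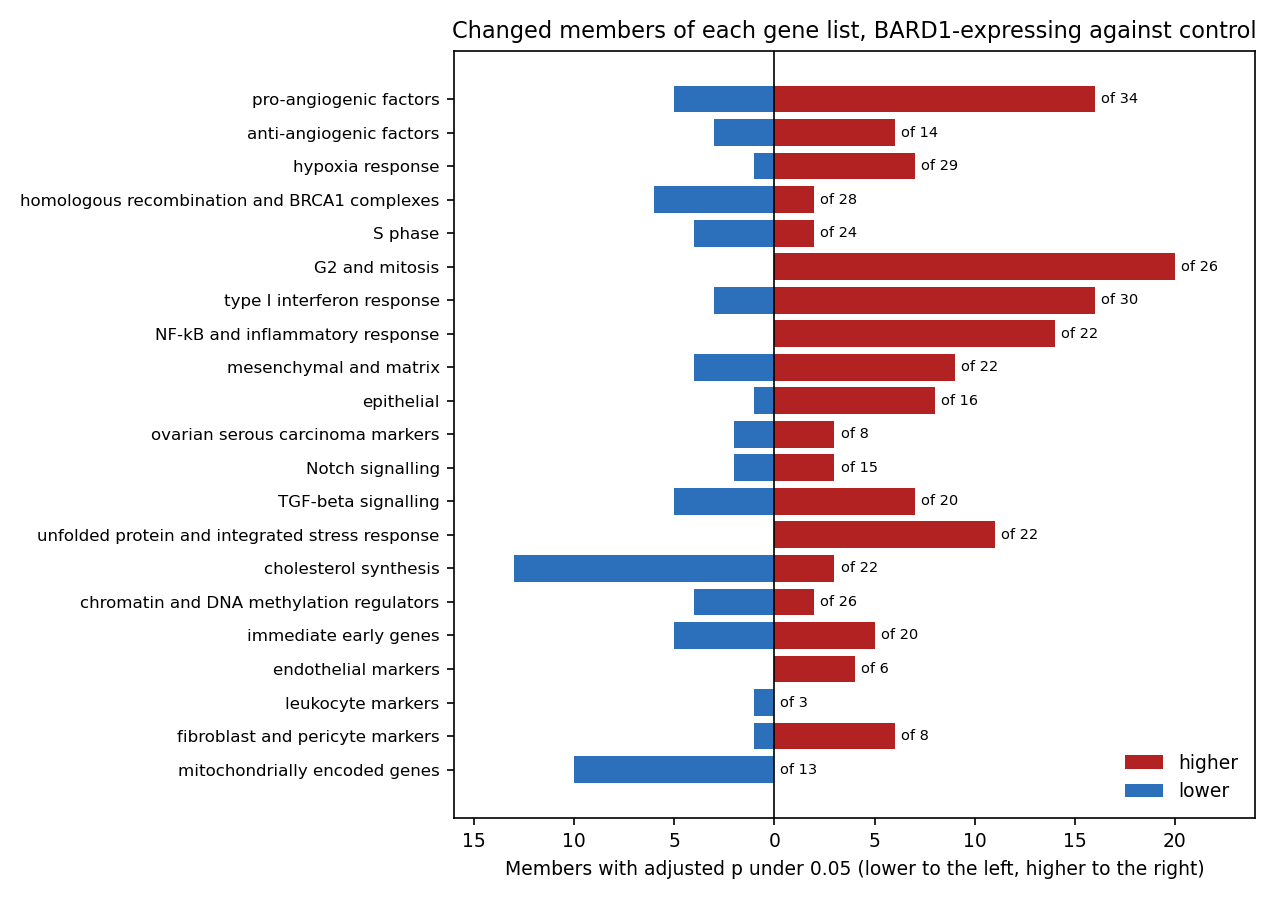
Number of members of each of 21 gene lists (vertical axis) that were higher (red, to the right) or lower (blue, to the left) in BARD1-expressing cells at an edgeR adjusted p under 0.05, with the number measured beside each bar. In the G2 and mitosis list 20 of 26 rose and none fell, and in the cholesterol synthesis list 13 of 22 fell and 3 rose.

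In all, 12 of the 22 lists passed camera with the preset correlation, 9 upwards and 3 downwards. With an estimated correlation 0 passed after adjustment and 5 had an unadjusted p under 0.05, and 14 passed with fry.

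Because the labels name both OVCAR8ip1 and SKOV3ip1, the level of ERBB2, which is known to be amplified in SKOV3, is given. ERBB2 stood at 95.7 ± 4.48 and 104 ± 4.63 CPM in control and BARD1-expressing cells (SD, n = 3 each, edgeR adjusted p = 0.108). No other line was measured here to set this level against.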

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

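Leaving out the genes of shifted stretches and thinning to an equal depth were chosen after the data had been seen, and all other alternatives before. The count of changed genes was 4460 and lay between 3317 and 4755 with 1 library left out (lowest without BARD1-expressing 3), and it was 3595 with DESeq2, 4366 with limma-voom, 4419 without a filter, 4014 without genes of shifted stretches and 3967 at equal depth. The count of genes changed at least 2-fold was 726, and lay between 559 with the stricter filter and 854 without a filter. The share of higher genes among the called ones stayed between 54.1% and 59.5%. BARD1 stayed higher and called in every setting, with log2 fold changes of 1.33 to 1.43. Chromosome 18 kept a median of -0.66 to -0.72 in every setting that tested it.

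The pro-angiogenic list kept its call in all alternatives but 1, at adjusted p-values of 0.000219 to 0.0191, and lost it with an estimated correlation (0.172). The anti-angiogenic list gained a call with fry (0.000326) and without a filter (0.0345) and had none otherwise, with values up to 0.313. Of the other 20 lists 11 passed, between 9 and 13 in the other settings, and 0 with an estimated correlation. For these changes the cause was not tested. Over 298 comparisons of these lists with an alternative, 259 kept side and direction, 21 lost the call and 10 gained one. The epithelial list, not called at 0.0526, gained a call in 6 settings (0.00103 to 0.0480), and the TGF-beta list in 3. The Notch list gained 1, with fry (adjusted p = 0.00216). The other 8 turned direction, all in lists without a call: leukocyte markers without a filter (0.2505), the S phase list without control 3 (0.949, range 0.687 to 0.987 over the libraries left out) and without genes of shifted stretches (0.881), and immediate early genes without control 1 (0.951), control 2 (0.895) or BARD1-expressing 2 (0.925, range 0.606 to 0.951), without genes of shifted stretches (0.706) and at equal depth (0.865). The ovarian marker list had a median of 0.0069, which fell below 0 with library sizes alone (-0.0028) and at equal depth (-0.16), and no other list median changed sign with the scaling.

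Of 161 called genes followed across the settings, 129 kept the call in every setting that tested them. The 1 call gained was that of ERBB2 without BARD1-expressing 1 (adjusted p = 0.0386). MT-RNR1, not called, changed sign without control 2 (-0.0014) and without BARD1-expressing 2 (-0.066), in a range of -0.066 to 0.15. Libraries with the same number did not deviate together (correlations of -0.112, -0.031 and -0.0088 over genes), and no library correlated best with the library of its own number. The fit with a replicate block called 3990 genes, 3943 of them shared with the fit without it, and gave BARD1 a log2 fold change of 1.37. Depth limits the low genes: BARD1-expressing libraries 1 and 3 held 12744310 and 15147685 counts, and 3 counts there are 0.235 and 0.198 CPM.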

Other observations

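The gene lists of this part and its tests were chosen after the gene table had been seen, except the tests of GC content and length, of library depth and of other splits of the libraries, which were set before their results were seen. Lists picked this way were tested on the data they were picked from, so their p-values are descriptive only.

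Basement membrane genes changed in both directions in BARD1-expressing cells, 9 of 21 higher and 4 lower (10 and 5 adjusted over the list alone). The collagen chain genes COL4A1 and COL4A2 rose from 89.5 ± 4.22 to 210 ± 6.94 CPM and from 221 ± 12.6 to 441 ± 36.1 CPM, and HSPG2, the perlecan gene, from 28.0 ± 2.58 to 81.0 ± 4.83 CPM (SD, n = 3 each). COL4A3 (-1.55 ± 0.436), COL4A4 (-1.51 ± 0.195) and LAMA3 (-1.41 ± 0.321, chromosome 18) were among the lower members. The list did not pass (camera adjusted p = 0.126 over the 4 lists of this part, and adjusted p = 0.386 with an estimated correlation). Its median log2 fold change (0.14) and its mean (-0.01) differed in sign, and it passed with fry (0.00525), without a filter (0.0358) and without genes of shifted stretches (0.0273).

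Antigen presentation genes rose in 8 of 21 cases and none fell (8 and 1 adjusted over the list alone, median log2 fold change 0.11, camera adjusted p = 0.0205, and adjusted p = 0.386 with an estimated correlation). The invariant chain gene CD74 (chromosome 5 stretch) stood at 0.0154 CPM in control cells, below the floor of each library, and 3.66 ± 0.166 CPM in BARD1-expressing cells, HLA-DMA rose from 1.2003 ± 0.292 to 4.91 ± 0.574 CPM, and HLA-B from 350 ± 11.5 to 445 ± 10.5 CPM (SD, n = 3 each). The call was lost without control 3 (adjusted p = 0.0795). Metallothionein genes rose in 4 of 5 measured cases, with the same count adjusted over the list alone, namely MT1M (1.47 ± 0.202), MT1F (1.13 ± 0.285), MT1E (0.45 ± 0.094) and MT2A (0.18 ± 0.063). Their list (camera adjusted p = 0.0356, and adjusted p = 0.386 with an estimated correlation) lost its call in 5 of 14 other settings, among them without control 3 (0.125), BARD1-expressing 2 (0.123) or BARD1-expressing 3 (0.0557). The calls of MT1E and MT2A were lost in some alternatives.

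Genes of chromosome 18 were lower as a block in BARD1-expressing cells, with a median log2 fold change of -0.68. Removing a trend on GC content and transcript length left the median at -0.69 (95% bootstrap interval -0.77 to -0.60) and thinning to equal depth at -0.67 (-0.77 to -0.59), which argues against either as the whole cause. None of 1000 shuffles of gene order gave a run as far from 0 as that of chromosome 18 (permutation p = 0.001, the smallest they can give). An even loss of the whole chromosome is argued against as well. The median was higher by 0.49 before its middle expressed gene than after it (-0.48 and -0.97). The 95% bootstrap interval of this difference was 0.39 to 0.56. All these bootstrap intervals resampled genes, which are not independent replicates, and do not measure the spread between libraries. Lower DNA copy number of different extent along the chromosome, and an effect of BARD1, stay open, since DNA was not analysed here.

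The mitochondrially encoded mRNAs were lower in BARD1-expressing cells, with a median log2 fold change of -0.85, and a difference in poly(A) capture and an effect of BARD1 stay open, both untested. A loss of exactly equal size in all mitochondrial RNA is argued against by the ribosomal RNA MT-RNR1, which lay 0.91 above the median of the 13 mRNAs (0.94 to 1.12 over pairs of libraries, from the median within each library). A broad loss is not, since 9 of the 15 other mitochondrial genes also fell, among them the ribosomal RNA MT-RNR2 (-1.26 ± 0.156), and 1 rose, the transfer RNA gene MT-TV (1.69 ± 0.181). A general fall of respiratory chain genes is argued against by the nuclear-encoded subunits. Of these, 7 of 55 rose and 2 fell (4 and 2 adjusted over the list alone). Their median was 0.092 (95% bootstrap interval over genes 0.069 to 0.11), above 0 in 2 of 3 BARD1-expressing libraries. That interval does not measure the spread between libraries. The list had a camera adjusted p of 0.0356, a call lost in 7 of 14 other settings, and adjusted p = 0.534 with an estimated correlation. The fallen ATP5F1A (-0.87 ± 0.051) and NDUFV2 (-1.22 ± 0.307) lie on chromosome 18, and the largest rises, NDUFA2 (0.66 ± 0.125) and UQCRQ (0.58 ± 0.1204), in the chromosome 5 stretch.

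AC005244.1 had reads in each control library and none in BARD1-expressing libraries. If its reads had been assigned to the parent gene DYNLT1 in BARD1-expressing cells, DYNLT1 would have gained them. The log2 fold change of DYNLT1 was 0.14 (95% interval 0.0011 to 0.28), and it was not called (edgeR adjusted p = 0.149). How large a gain those reads would give depends on the level of DYNLT1, which is not given here, so this stays undecided. Loss of the surrounding gene is argued against by MAP2K4, with a log2 fold change of 0.34 (0.17 to 0.51). A loss limited to the pseudogene, or descent of the BARD1-expressing cells from cells that lacked this transcript, may account for the pattern, and neither was tested here.

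The 6 libraries split into 3 and 3 in only 10 ways, the real one included, too few for a share under 0.05. The real split was the 1 of the 10 with the most changed genes (4460, the highest other 0), the most genes changed at least 2-fold (726, the highest other 0) and the most lists past the threshold (12, the highest other 7). At an unadjusted edgeR p under 0.05 it gave 5951 genes, and the highest other split 728. Every other split mixed control and BARD1-expressing libraries on each side, so the difference between the groups entered the spread within its sides. The low gene counts of those splits therefore cannot show how many of the 4460 calls are false.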
